A study of Mus musculus with 2 samples.

How the data were processed

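Gene expression was measured in the liver of female C57BL/6 wild-type mice, 8 weeks old, 24 h after a sham operation or after 30 min of warm bilateral renal ischemia with reperfusion. Per the labels, 100 mg of frozen liver from 3 mice of a group was pooled, total RNA was extracted with Trizol, and biotinylated cRNA was prepared from 8 ug of total RNA for Affymetrix arrays. Each group was 1 pool on 1 array, so the 2 arrays hold no replicate, and their number limits the precision. What the labels name as group was used as it stands.

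The values deposited by the authors are signal intensity values per probe set on a linear scale, from 0.6 to 127786.6. The software that made them is not given in the sources used here. On each array the mean signal after leaving out the lowest and highest 2% of probe sets was 500.00, so the authors had scaled the arrays to a common target. A common target removes any true difference in the total amount of mRNA between the pools. Of 45101 probe sets, 64 are array controls. Of the other 45037, 34945 were named by 1 gene symbol through the platform annotation, 932 by several and 9160 by none. The symbols were compared through Entrez gene numbers with a RefSeq gene table of assembly GRCm38.p6, which matched 34754 probe sets and altered 0 symbols. The table of values names no genome build, so no chromosome positions are given.

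The authors' scaling was kept. Values were taken as log2(signal + 71.8), where 71.8 is the 25th percentile of the table, and the difference is AKI minus sham. Each gene is represented by the probe set with the highest mean level, and a gene was counted when this probe set was at or above the median of non-control probe sets on at least 1 array (225.7 sham, 231.8 AKI). Of 18194 named genes, 13128 passed this level filter. With 1 array per group no test between groups can be made, and no p-value is given. Probe sets of the same gene give the only repeat measurement. Their SD within genes is a measurement error, partly from different transcripts, and leaves out the animals. It was smaller for strongly expressed genes, 0.52 in the highest of 4 level classes and 0.79 in the lowest.

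Before the data were examined, 47 gene lists of liver functions, signalling responses, cell type markers and reference genes were fixed, with 933 entries in all. Of these entries 837 were matched to a named gene and 776 passed the level filter. For each list with at least 3 measured genes, the median difference was set against medians of 10000 random lists of the same size drawn from the same 20 level classes, and its percentile is given. The 95% bootstrap interval of a list median comes from 10000 draws of its genes and covers the spread between genes, not between mice. Genes were named by a rule also fixed beforehand, which took the 15 largest positive and 15 largest negative differences among genes whose probe sets all went the same way, and up to 4 members of each list with the largest absolute difference, or more to complete a count of 5 or fewer. All reference genes were open to naming. Genes of the families described in the closing section were chosen after their values were seen.

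The alternatives fixed beforehand began with median centring, quantile normalization and lowess centring (fraction 0.3) of the differences. The level filter was dropped or set at the 75th percentile. The mean of a gene's probe sets was also used, as was a pseudocount of 1 or of the table median, 228.7. A further alternative left out probe sets with the suffix _s_at, _x_at or _a_at, which may match several transcripts, of the same gene or of others. Centring on 18 hybridization control probe sets, centring on the reference genes, and lists without members shared with other lists were added after the data were seen. Leaving Cd14 out of the macrophage list was also decided then.

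The computation was tested on simulated data with noise of SD 0.7 in 12772 genes. Of genes set to an 8-fold difference 100% passed the 2-fold threshold, of genes set to 2-fold 43.6%, and of unchanged genes 11.5%, while 0.143% of unchanged genes passed 4-fold. A list of 25 genes set 2-fold higher, of which 22 were measured, came out at percentile 100 and an unchanged list of 25 at 44.3. The simulated noise was independent between genes and had the same SD at every level, unlike the data. It therefore does not show how the percentile behaves for lists whose genes vary together. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.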

Results

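The study asked how gene expression in the liver differs after injury to the kidneys. Female C57BL/6 wild-type mice, 8 weeks old, had either a sham operation or 30 min of warm bilateral renal ischemia followed by reperfusion, which causes acute kidney injury (AKI). Livers were taken 24 h later. Frozen liver from 3 mice of a group was pooled, and each pool was measured on 1 Affymetrix mouse expression array, so there were 2 arrays, 1 per group. The median signal was 225.80 on the sham array and 231.80 on the AKI array, and the mean signal after trimming 2% of the probe sets at each end was 500.00 on both. Across all probe sets, Spearman's rho between the arrays was 0.837, where probe sets are not independent replicates. Neither group has a replicate array. Differences between the pools therefore include variation between mice that cannot be estimated, and they have no p-value. The words "higher" and "lower" below describe these 2 pools. All differences are log2 values, AKI minus sham, on the log2(signal + 71.8) scale, which understates the differences of weakly expressed genes.

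Among genes whose probe sets all went the same way, the largest difference was that of Pdk4, the kinase that inhibits the pyruvate dehydrogenase complex. Its signal was 271.6 in the sham pool and 47983.5 in the AKI pool, a difference of 7.13. The acute phase genes Saa2 (6.24) and Lcn2 (5.89), the chemokine gene Cxcl2 (5.57), the lipopolysaccharide co-receptor gene Cd14 (5.54) and the transcription factor gene Egr1 (5.38) came next. Igfbp1, which encodes a secreted protein that binds insulin-like growth factors, had a signal of 2813.1 in the sham pool and 78631.3 in the AKI pool (4.77). The other genes among the 15 with the largest positive differences were Denn2b, Sult1e1, Rab30, Il1r1, Tnfaip3, Plscr1, Socs3 and Tnfrsf12a, between 4.71 and 5.24. The probe sets of Rab30 spanned 0.80 to 5.15. Pdk4, Saa2, Lcn2, Cxcl2, Cd14, Egr1, Igfbp1, Denn2b, Sult1e1 and Il1r1 each had only 1 probe set past the level filter. Agreement between probe sets could not be checked for them.

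On the scale used here, the largest negative difference was that of Idi1 (-5.12), an enzyme of isoprenoid and cholesterol synthesis. Its signal was 10033.7 in the sham pool and 218.3 in the AKI pool. Next were the transcription factor gene Klf15 (-4.86), the choline dehydrogenase gene Chdh (-4.65) and Cyp7a1 (-4.52). Cyp7a1 is the rate-limiting enzyme of the classical bile acid pathway. This order depends on the pseudocount. The signal ratio, sham over AKI, was 46.0 for Idi1 but 78.8 for Chdh and 73.9 for Klf15. It was also larger for Nfic (59), Rtp3 (58.8) and Anks4b (48.6). The AKI signals of these 5 genes were weak, from 21.7 to 44.9, so their exact rank is uncertain. The gluconeogenic genes Pck1 (-4.48) and G6pc (-4.35) were also among the 15 most negative, although the probe sets of Pck1 spanned -4.48 to -0.48. The others were Akr1c14, Hebp1, Bhmt2, Aldh8a1, Nfic, Serpina4-ps1, Rtp3, Hmgcs1 and Anks4b, between -4.35 and -3.72. Klf15, Chdh, G6pc, Akr1c14, Hebp1, Rtp3 and Anks4b each had only 1 probe set past the level filter.

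**Figure D1:**
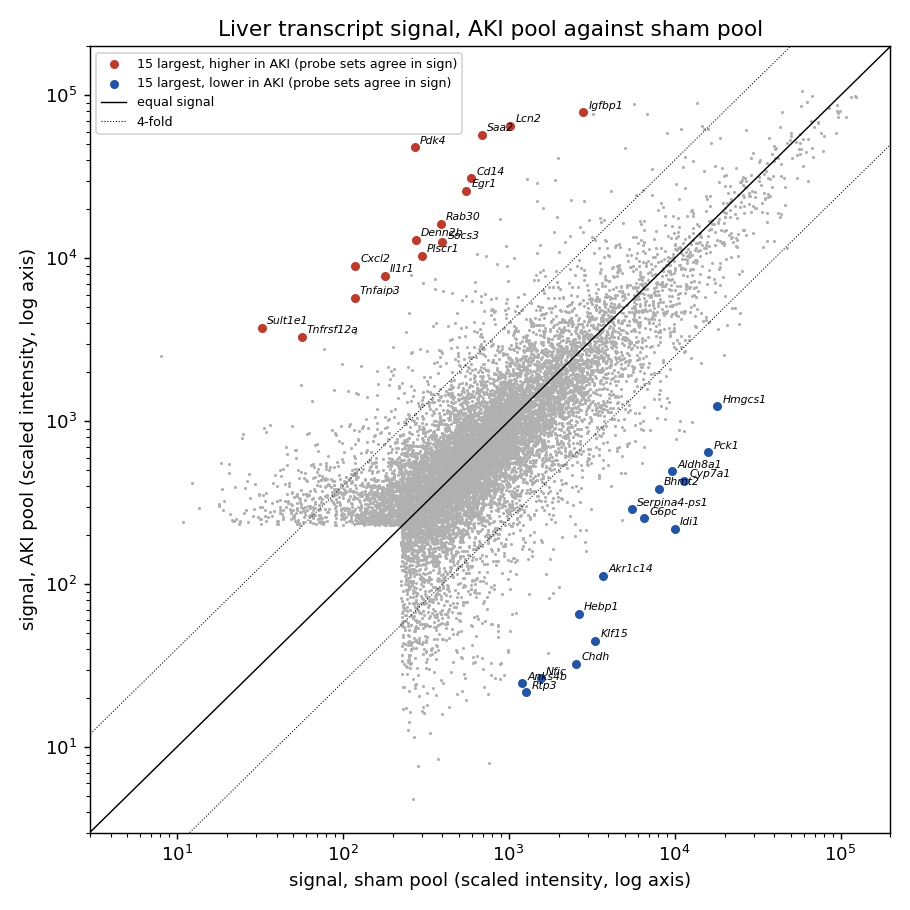
Each point is 1 of the 13128 genes past the level filter, with its signal in the sham pool on the x axis and in the AKI pool on the y axis, both on log scales. The named genes are those with the largest log2(signal + 71.8) differences each way among genes whose probe sets all went the same way, with Pdk4 at a difference of 7.13 and Idi1 at -5.12. Genes with only 1 probe set past the filter counted as going the same way.

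Of 13128 genes past the level filter, 1370 were at least 2-fold higher and 1634 at least 2-fold lower in the AKI pool. At 4-fold the counts were 275 and 311, and at 8-fold 72 and 57. The only repeat measurement is a second probe set of the same gene on the same arrays. Over 5149 genes with at least 2 probe sets past the filter, the differences of the probe sets had an SD within genes of 0.65 and a Pearson r of 0.56 across genes. This SD was 0.79 in the lowest of 4 level classes and 0.52 in the highest. Normal noise with the SD of each gene's level class would alone put 948 genes past 2-fold in each direction, 36.7 past 4-fold and 0.41 past 8-fold, so a single gene at 2-fold was not distinguishable from measurement error. Among genes past 4-fold with several probe sets, all probe sets went the same way for 98 of 120 higher genes and 92 of 117 lower genes. All probe sets passed 4-fold for only 34 of the 120 and 33 of the 117. The split between higher and lower depended on the scaling. With the arrays centred on 18 hybridization control probe sets it was 2235 higher and 1057 lower, and with centring on 13 reference genes it was 930 and 2381. Higher genes made up 67.9% and 28.1% of these counts, against 45.6% with the authors' scaling. The median over all genes was 0.28 and -0.27 under these centrings, against -0.02, and each list median below moves with them by 0.30 upwards or by 0.25 downwards. This turns the sign of the heat shock, oxidative phosphorylation, iron, clock, proliferation, hepatokine, pericentral, B cell, stellate cell, erythroid and pancreatic medians, but of no other list. Each list's percentile among random lists stays as it is, since the random lists move too.

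Genes of the acute phase response, mostly those of plasma proteins the liver makes more of in inflammation, were higher in the AKI pool. The median difference of 29 measured genes was 0.88 (95% bootstrap interval over genes 0.53 to 2.37), above all 10000 random lists of the same size and level. At least 2-fold higher were 14, among them Saa2, Lcn2, Saa1 (4.55) and Steap4 (4.23), and 2 were at least 2-fold lower, Saa4 (-2.06) and Crp (-1.81). Without probe sets that may match several transcripts the median was 0.58. Chemokines and targets of NF-kB, the transcription factor of inflammatory signalling, had a median of 1.91 over 18 genes (0.73 to 2.38), also above all random lists, with 11 genes at least 2-fold higher and 0 lower. Cxcl2, Tnfaip3 (4.93), Cxcl1 (3.94) and Nfkbiz (3.54) led, and without the level filter the median was 0.88. Another probe set of Nfkbiz was at 0.35. Targets and feedback genes of STAT3, which carries the signal of interleukin-6, had a median of 1.15 over 14 genes, with 8 at least 2-fold higher, among them Il1r1 (4.97), Socs3 (4.75), Pim1 (3.04) and Junb (2.91). Genes of proteins whose synthesis usually drops in inflammation had a median of -0.43 over 11 genes (-0.62 to -0.12), with 10 of them below 0. This median was not outside random lists, at percentile 12.5, and only Igfals (-2.78) was at least 2-fold lower. Complement and coagulation factors had a median of -0.53 over 24 genes at percentile 1.23. Mbl1 (-1.50) and F11 (-1.09) were at least 2-fold lower, and the other 22 differed by less than 2-fold. Interferon-stimulated genes had a median of -0.37 over 19 genes at percentile 2.74, inside the central 95% of random lists, and went both ways. Ifi35 (-3.39) and Igtp (-2.42) were lower and Rsad2 (2.07) was higher. Probe sets spanned -3.39 to -0.79 for Ifi35 and 0.18 to 2.07 for Rsad2.

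Immediate early and endoplasmic reticulum stress genes were higher as well. Immediate early genes, which are transcribed within minutes of a stimulus, had the highest median of the lists, 2.82 over 17 genes, with 14 at least 2-fold higher, including Egr1, Ier3 (4.54), Klf6 (4.22) and Maff (3.23). Targets of p53 and growth arrest genes had a median of 0.68 over 15 genes at percentile 99.94, but with a bootstrap interval of -0.16 to 2.63 and 5 genes below 0, and with Gadd45a (4.25), Cdkn1a (3.70), Btg2 (2.95) and Gadd45g (2.63) the highest. Genes of the endoplasmic reticulum stress response had a median of 0.95 over 23 genes, above all random lists. Among the 11 that were at least 2-fold higher were Creld2 (3.34), the chaperone gene Hspa5 (2.71), Manf (2.39) and Dnajb9 (2.02), while Derl3 (-1.14) was lower. Heat shock protein and co-chaperone genes went both ways, with a median of -0.29 over 13 genes at percentile 22.1. Bag3 (2.40), Hsp90aa1 (1.44) and Hspb8 (1.01) were higher, and Hsph1 (-2.14), Cryab (-1.28), Chordc1 (-1.21) and Dnaja1 (-1.15) were lower. Another probe set of Hsp90aa1 was at 0.12. The glucocorticoid receptor list had a median of 0.90 over 16 genes, above all random lists, though its bootstrap interval ran from -0.12 to 3.47. It was led by Lcn2, Sult1e1 (5.20), Igfbp1 and Cdkn1a, whereas Tsc22d3 (-1.87) and Tdo2 (-1.47) were lower. Once members that other lists also hold were left out, 8 genes remained with a median of 0.16 at percentile 79.0. Tsc22d3 had a difference of 0.29 when probe sets that may match several transcripts were left out. Hypoxia-response genes had a median of 0.28 over 13 genes at percentile 92.0, and of -0.15 at the stricter level filter. Slc2a1 (2.19), Ndrg1 (1.88), Adm (1.41) and Higd1a (1.34) were higher and Vegfa (-1.90) was lower, with its other probe set at 0.22. The 5 probe sets of Ndrg1 spanned 0.04 to 2.54.

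Lipid synthesis genes were lower in the AKI pool. The cholesterol synthesis list had a median of -1.45 over 20 genes (-1.83 to -0.70), below all 10000 random lists, with 12 genes at least 2-fold lower and 0 higher. Idi1, Hmgcs1 (-3.79), which makes the substrate of the rate-limiting reductase, Mvk (-2.87) and Msmo1 (-2.81) had the largest differences. Fatty acid synthesis genes had a median of -1.19 over 21 genes (-1.68 to -0.82), also below all random lists. Of these, 13 were at least 2-fold lower, among them Acacb (-2.91), Elovl6 (-2.60), Dgat2 (-2.41) and Acly (-2.37), and 1 was higher, the desaturase gene Scd1 (1.20). Elovl6 and Acly each also had a probe set in the other direction, at 0.53 and 0.38. The list of fatty acid oxidation genes and targets of PPARalpha, the nuclear receptor that controls them, had a median of -0.63 over 32 genes (-0.87 to -0.37) at percentile 0.07. Centring on hybridization controls made this median -0.33. In this list 7 genes were at least 2-fold lower, including Acot3 (-2.60) and Bdh1 (-2.35), and 4 were higher, Pdk4, the lipid droplet genes Cidec (2.98) and Plin2 (2.04), and Angptl4 (1.18).

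Bile acid synthesis genes had a median of -1.52 over 17 genes, and of -1.39 over the 13 that no other list holds, both below all random lists. Of the 17, 12 were at least 2-fold lower and 0 higher. Cyp7a1 was the lowest, with signals of 11475.1 and 433.2, and Cyp8b1 was at -2.62. The 17 genes include nuclear receptor genes that regulate this pathway, of which Nr0b2 (-3.55) and Nr1h4 (-2.31) were lower. Among hepatic transporters the median was -1.14 over 21 genes, below all random lists. The bile salt export pump gene Abcb11 (-2.64), Slco1b2 (-2.61) and Abcg5 (-1.91) were among the 11 that were at least 2-fold lower, and Abca1 (2.05), Abcb1a (1.24) and Abcc4 (1.07) were higher. Slco1b2 had another probe set at 0.48. The signals of Abcc4 were weak, 102 in the sham pool and 294.1 in the AKI pool. Liver transcription factors and nuclear receptors had a median of -0.96 over 20 genes, below all random lists, with 9 at least 2-fold lower, including Nr1i3 (-2.61) and Onecut1 (-2.09), and 0 higher.

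**Figure D2:**
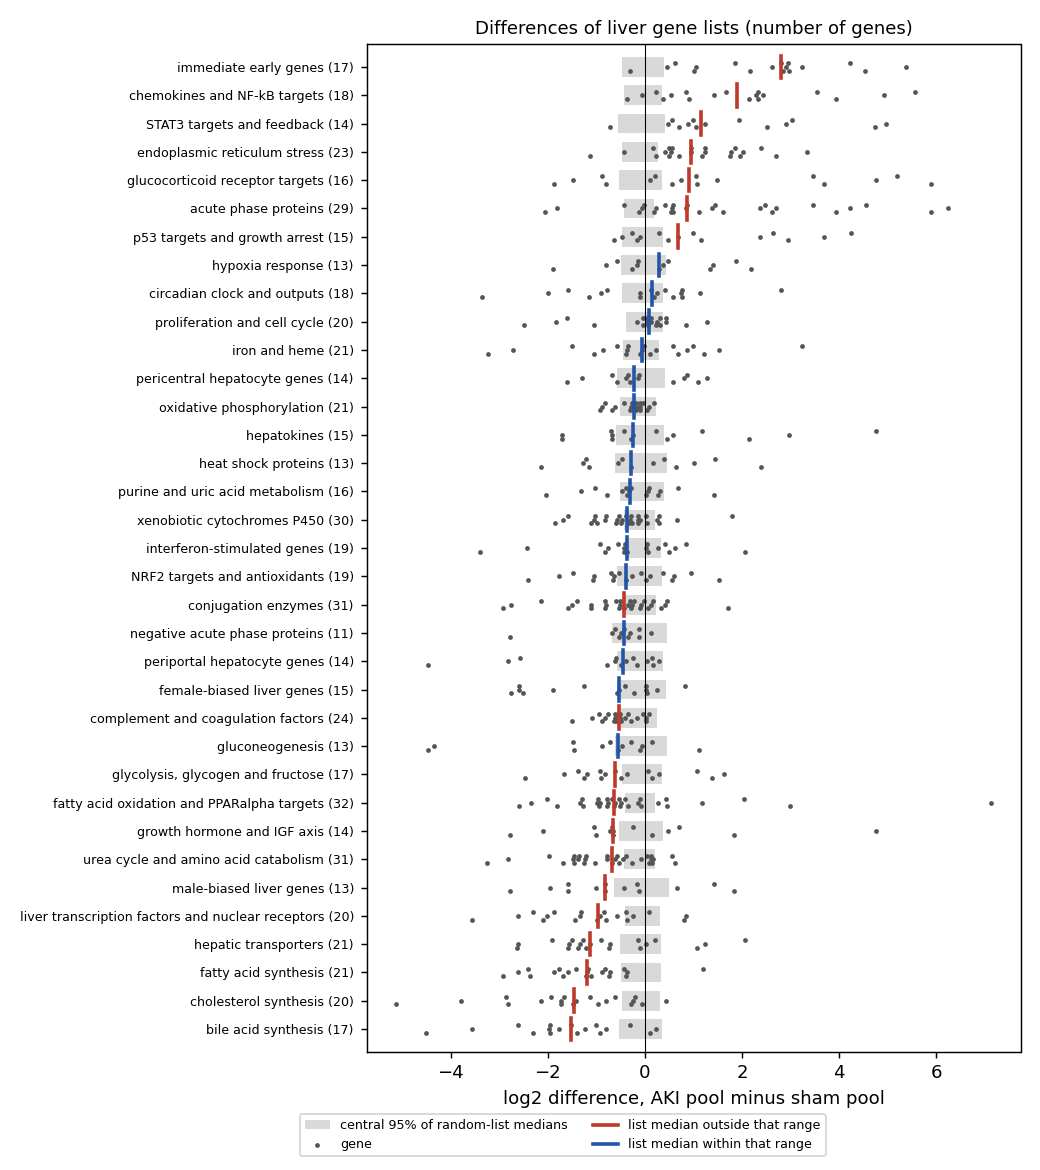
Log2 differences, AKI minus sham, of the genes of each fixed list (points), with the list median (line) and the central 95% of medians of 10000 random lists of the same size and level (grey bars). Medians run from -1.52 for bile acid synthesis to 2.82 for immediate early genes, and red lines mark medians outside the grey bar.

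In carbohydrate metabolism, the gluconeogenesis list as a whole stayed inside the random range, with a median of -0.55 over 13 genes at percentile 4.16. Its differences were uneven. Pck1 and G6pc were lower by more than 4 on the log2 scale, Gpd1 (-1.47) and the glucose 6-phosphate transporter gene Slc37a4 (-1.45) by less, and Crtc2 (1.12) was higher. Glycolysis, glycogen and fructose genes had a median of -0.61 over 17 genes at percentile 0.555. Ppp1r3b (-2.47), Tpi1 (-1.67), Gys2 (-1.37), Slc2a2 (-1.25) and Pygl (-1.20) were lower, and Pfkfb3 (1.62), Ppp1r3g (1.38) and Ldha (1.08) were higher. Genes of the urea cycle and amino acid catabolism had a median of -0.68 over 31 genes at percentile 0.025, with 13 at least 2-fold lower and 0 higher. The lowest were Kynu (-3.25), Hal (-2.82), Cbs (-1.97) and Prodh (-1.68). Purine metabolism genes had a median of -0.30 over 16 genes at percentile 13.5, with urate oxidase, Uox (-2.03), Paics (-1.31) and Adk (-1.03) lower and Ampd2 (1.43) higher. Adk also had a probe set at 0.73. Oxidative phosphorylation genes had a median of -0.23 over 21 genes at percentile 35.5. None of them differed by 2-fold, and the largest difference was that of Uqcrfs1 (-0.93).

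The list of xenobiotic cytochromes P450 and flavin monooxygenases had a median of -0.36 over 30 genes (-0.58 to -0.13) at percentile 5.63, inside the central 95% of random lists. The median was -0.06 with centring on hybridization controls and -0.61 with centring on reference genes. At least 2-fold lower were 6 genes, including Fmo1 (-1.85), Fmo5 (-1.69) and Cyp2u1 (-1.58), and Cyp2b10 (1.81) was higher. Another probe set of Cyp2u1 was at -0.16. Conjugation enzymes had a median of -0.43 over 31 genes at percentile 1.995, and of -0.33 at percentile 7.24 without shared members. Nat2 (-2.93), Sult3a1 (-2.75) and Ugt2b35 (-2.13) were among 8 that were at least 2-fold lower, and Nnmt (1.72) was higher. Antioxidant genes and targets of NRF2 had a median of -0.38 over 19 genes at percentile 11.7. Nqo1 (-2.41), Gclc (-1.49), Cat (-1.07) and Gclm (-1.04) were lower and Hmox1 (1.54) was higher. The main probe set of Nfe2l2, the gene of NRF2 itself, was at -1.77, but its other probe set was at 3.05.

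Iron and heme genes as a group were at -0.06 over 21 genes at percentile 57.0, with single members far apart. The zinc and iron importer gene Slc39a14 (3.24), Hmox1 and Tfrc (1.22) were higher, whereas Hjv (-3.23), which encodes the hemojuvelin co-receptor, the iron exporter gene Slc40a1 (-2.72), Blvrb (-1.49) and Urod (-1.06) were lower. Another probe set of Tfrc was at 0.12. Circadian clock genes and their outputs had a median of 0.15 over 18 genes at percentile 80.9. Nfil3 (2.80) and Bhlhe40 (1.14) were higher, and the clock-controlled Dbp (-3.35), Tef (-1.99), Usp2 (-1.58) and Hlf (-1.14) were lower. Proliferation and cell cycle genes had a median of 0.10 over 20 genes at percentile 69.0, with Tk1 (-2.48), Cdk1 (-1.84), Ccnd1 (-1.61) and Cdc20 (-1.05) lower and Mcm4 (1.28) higher.

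Genes of the growth hormone and IGF axis had a median of -0.65 over 14 genes at percentile 0.85. Igfals, Onecut1, Igfbp2 (-1.05) and Stat5a (-1.01) were lower, and Igfbp1 and Bcl6 (1.83) were higher. Another probe set of Bcl6 was at 0.37. The list median was 0.48 without probe sets that may match several transcripts, and at percentile 3.82 without shared members. Lists of genes with a known sex bias in mouse liver both had negative medians. The male-biased list had a median of -0.82 over 13 genes at percentile 0.64, though at percentile 31.4 over the 4 genes no other list holds. The female-biased list had a median of -0.53 over 15 genes at percentile 3.30, and of -0.82 at percentile 0.79 over the 8 genes no other list holds. Hsd3b5 (-2.78) and Cyp7b1 (-1.96) had the largest differences in the male-biased list, and Sult3a1, Hao2 (-2.60), Acot3 and Abcd2 (-2.50) in the female-biased list. In the male-biased list 2 genes were at least 2-fold higher, Bcl6 and Cyp4a12a (1.42). The signals of Cyp4a12a were weak, 66.1 in the sham pool and 296.9 in the AKI pool. Hepatokines, proteins that the liver secretes as signals, had a median of -0.25 over 15 genes at percentile 25.9. Without probe sets that may match several transcripts it was 0.45. Igfbp1, Fst (2.98), Agt (2.16) and Angptl4 were higher and Inhba (-1.71) and Enho (-1.71) lower, with a probe set of Enho at 0.55. Pericentral hepatocyte genes had a median of -0.22 over 14 genes at percentile 28.1 and periportal genes of -0.44 over 14 at percentile 7.58. Glul (1.28), Slc1a4 (1.09), Slc1a2 (-1.59) and Gulo (-1.30) from the pericentral list passed 2-fold, as did Pck1, Hal and Aldh1b1 (-2.57) from the periportal list. Glul had another probe set at -0.27. The signals of Slc1a4 were weak, 98.9 in the sham pool and 290.6 in the AKI pool.

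Markers of other cell types were compared in the same way, since liver tissue holds more than hepatocytes. Neutrophil markers were higher, with a median of 0.76 over 11 genes at percentile 99.95, and of 0.51 to 1.58 across the other settings. S100a8 (3.17), S100a9 (2.72), Il1r2 (2.05), Mmp9 (1.13) and Ngp (1.12) passed 2-fold. Sinusoidal endothelial markers were lower, with a median of -0.59 over 15 genes at percentile 1.155, and with Clec4g (-2.08), Oit3 (-1.86) and Stab1 (-1.55) among 6 that were at least 2-fold lower and Lyve1 (1.79) higher. Markers of Kupffer cells and macrophages had a median of -0.46 over 15 genes at percentile 2.895. Cd14 and Marco (1.46) were at least 2-fold higher, and Clec4f (-1.37), Cd5l (-1.24) and C1qa (-1.01) at least 2-fold lower. The percentile was 2.07 without Cd14, the member with the largest positive difference. That omission was chosen after the data were seen.

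Monocyte markers (0.48 over 6 genes, percentile 91.4) and T and NK cell markers (0.49 over 9, percentile 94.9) stayed inside the random range. Cx3cr1 (1.45) passed 2-fold in the first list, and Nkg7 (1.27) and Il2rb (1.09) in the second. The AKI signals of Cx3cr1 (278.9) and Nkg7 (266.1) were weak. They were below the 291.6 of the Y-linked Kdm5d in the same female pool, so these 2 differences may be background. B cell markers were at -0.08 over 8 genes at percentile 39.7, with Blk at -1.94. Stellate cell and matrix markers were at -0.13 over 15 genes at percentile 38.45, with Lrat (-1.74) and Ngfr (-1.12) lower. Only 2 cholangiocyte markers passed the level filter, Sox9 (2.58) and Epcam (0.40). Markers from outside the liver gave a median of -0.22 over 7 pancreatic acinar genes (percentile 30.1), of 0.42 over 6 adipocyte genes (percentile 89.3), with Fabp4 (2.46) and Plin4 (1.53) past 2-fold, and of -0.06 over 4 erythroid genes (percentile 41.2). The probe sets of Fabp4 spanned 0.37 to 2.46. The 13 housekeeping reference genes had a median of 0.25 at percentile 92.2, and of -0.03 without probe sets that may match several transcripts. Tfrc and Ywhaz (1.20) passed 2-fold among them, while Actb was at 0.25 and Eef1a1 at -0.10. Ywhaz and Actb each also had a probe set in the other direction, at -0.40 and -0.47.

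**Figure D3:**
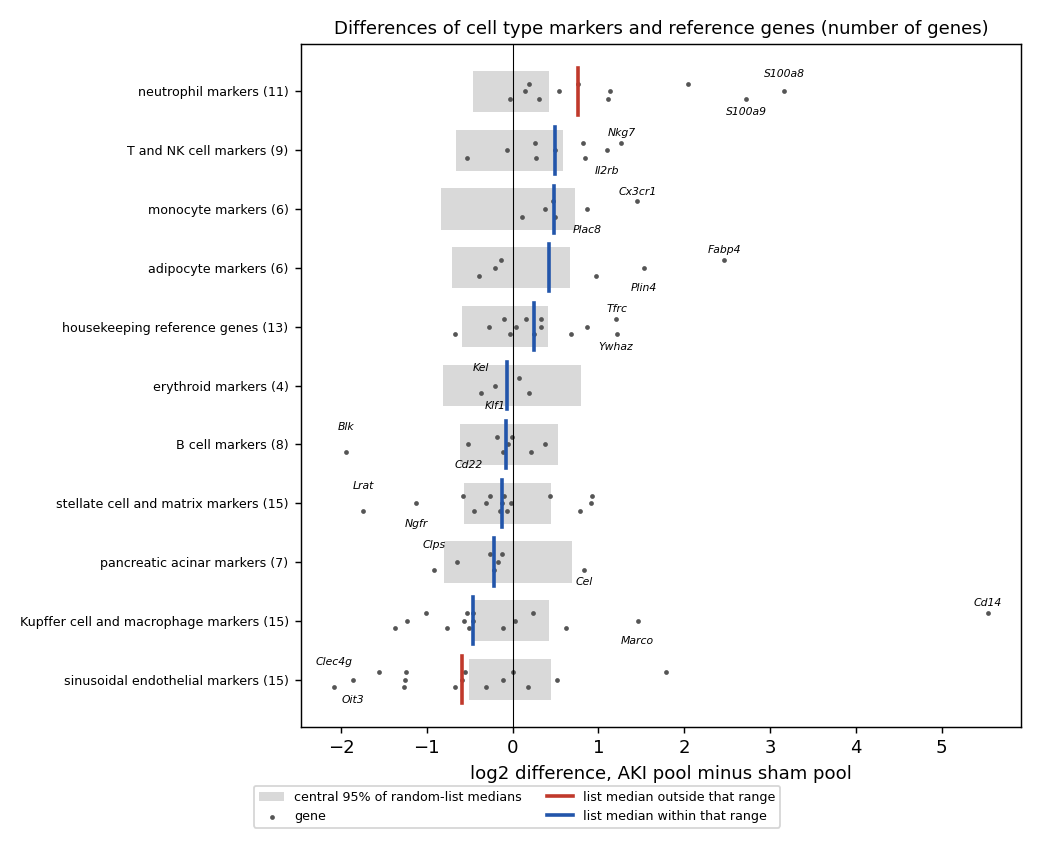
Log2 differences, AKI minus sham, of cell type markers and reference genes (points), with the list median (line) and the central 95% of medians of 10000 random lists (grey bars). Neutrophil markers lie above their grey bar with a median of 0.76 and sinusoidal endothelial markers below theirs with a median of -0.59.

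In all, the medians of 21 of the 46 lists with at least 3 measured genes lay outside the central 95% of random lists, 8 above and 13 below. By chance 2.3 would, if genes of a list varied together no more than randomly drawn genes. Genes of the same function may vary together more than that, so 2.3 can be too low. Many lists share members, and a percentile describes these 2 arrays, not other mice.

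Signs of RNA quality differed between the arrays. The ratio of the 3' to the 5' probe set signal was 1.61 in the sham pool and 2.24 in the AKI pool for Actb, 0.860 and 1.05 for Gapdh, and 3.66 and 3.50 for pyruvate carboxylase. In both pools Xist was well measured, with highest signals of 9778.5 and 10655.3, and the highest signal of the Y-linked genes Eif2s3y, Kdm5d and Uty was 291.6. Both pools are labelled female.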

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

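Probe sets that carry no single gene symbol here were not used in any comparison, and some of them differed between the pools. Of 4645 such probe sets past the level filter, 88 (1.89%) had a signal at least 4-fold higher in the AKI pool than in the sham pool and 52 (1.12%) at least 4-fold lower. Among 21386 probe sets with 1 symbol the counts were 529 (2.47%) and 565 (2.64%). No explanation was tested for the probe sets without a symbol.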

How the results depend on the processing

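The 8 main list medians, the counts past 2-fold, the probe set agreement and the count of other lists outside the random range (16, and 14 to 18 elsewhere) were recomputed under 11 other settings, of which the centrings on control probe sets and on reference genes were chosen after the data were seen. The medians of acute phase, chemokine, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, P450 and negative acute phase genes had the same sign under every setting. The proliferation median did not, and was -0.15 with centring on reference genes. Of 131 such values 100 stayed within a set limit of the main value, as did 336 of 416 for the other lists and 2329 of 2420 for named genes. The limit was a ratio for counts and a spread for the other values. The 31 of 131 values past it came from 11 of the 12 results. No paired analysis was possible because each group has 1 array, and leaving out a replicate was not possible for the same reason. Weak signals limit the results, since probe sets of one gene had an r of 0.30 in the lowest level class and 0.79 in the highest.

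The median of acute phase genes (0.88) was 1.04 with lowess centring and 1.11 with the mean of probe sets. Without probe sets that may match several transcripts it was 0.58. That of chemokines and NF-kB targets (1.91) was 0.88 without a level filter and 1.61 with the mean of probe sets. It was 2.22 without the several-transcript kind and 1.55 with the pseudocount at the median. The agreement r (0.56) was 0.43 without a level filter, 0.73 at the 75th percentile and 0.46 without the several-transcript kind. The same r was 0.51 with a pseudocount of 1 and 0.62 with the pseudocount at the median. It could not be computed for the mean of probe sets. With that larger pseudocount 841 genes were at least 2-fold higher and 1063 lower, as a larger pseudocount shrinks every difference. The filters, too, act by which genes enter. For the other settings the cause was not tested.

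Centring on hybridization controls adds 0.30 to every difference. It gave 2235 genes higher and 1057 lower, and medians of 1.18 for acute phase, -0.13 for negative acute phase, 2.21 for chemokines, -0.058 for P450, -1.15 for cholesterol synthesis, -0.89 for fatty acid synthesis, -0.33 for fatty acid oxidation and 0.40 for proliferation. It turned the median of hepatokines (0.052), the median of heat shock proteins (0.018) and the median of oxidative phosphorylation (0.078) positive. Centring on reference genes takes 0.25 off, with medians of 0.63, 1.66, -0.61, -1.70, -1.44 and -0.88 for acute phase, chemokines, P450, cholesterol synthesis, fatty acid synthesis and fatty acid oxidation.

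Without probe sets that may match several transcripts, some medians changed sign. These were hypoxia genes (-0.15), the growth hormone and IGF axis (0.48), hepatokines (0.45) and reference genes (-0.028). Among the named genes that did so were Cd8a (-0.19), Tsc22d3 (0.29) and Actb (-0.47). The hypoxia median was also -0.15 at the 75th percentile filter, and Nfe2l2 was at 0.64 with the mean of its probe sets. The cause was not tested.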

Other observations

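All gene families and tests in this part were chosen after the results were seen.

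Genes that build ribosomes and those of the mitochondrial ribosome differed in opposite directions. Among 45 nucleolar and ribosome assembly genes, picked by gene symbol, the median difference was 0.62, above all 10000 random lists, and 11 were at least 2-fold higher in the AKI pool, including Nop58 (1.96), Utp20 (1.83), Gar1 (1.80) and Rrp1b (1.79). Utp25 (-2.18) was the 1 gene at least 2-fold lower. Genes with symbols of translation initiation factors and their regulators had a median of 0.29 over 44 genes at percentile 99.4, with Eif1a (1.91), Eif2ak3 (1.87) and Eif4a1 (1.74) the highest. In contrast, 76 mitochondrial ribosomal protein genes had a median of -0.48, below all random lists. Of these 61 were below 0 and 14 at least 2-fold lower, among them Mrps16 (-2.13) and Mrps27 (-1.77), while Mrps18b (1.62) was higher. The sign of these 3 medians was the same under all scalings tried. Cytosolic ribosomal protein genes had a median of 0.35 over 42 genes at percentile 99.95. Over the 20 that remained without probe sets that may match several transcripts it was only 0.14, at percentile 80.9. Proteasome subunits were at -0.005 over 38 genes, with a sign that depended on the scaling.

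Aldehyde dehydrogenases were lower as a family. They had a median of -0.77 over 16 genes at percentile 0.14, led by Aldh8a1 (-4.10), Aldh1b1 (-2.57) and Aldh3a2 (-2.51), with Aldh9a1 (1.05) higher. Hydroxysteroid dehydrogenases had a median of -0.66 over 17 genes at percentile 0.94, with Hsd3b5 (-2.78), Hsd3b3 (-2.73) and Hsd3b2 (-2.01) the lowest. This median did not stay outside random lists. With the mean of probe sets it was -0.50 at percentile 4.52, and without probe sets that may match several transcripts it was at percentile 3.16.

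Bile acid synthesis genes were lower in the AKI pool. A smaller share of hepatocytes in the tissue would lower other hepatocyte genes as much, yet the median of 22 P450 genes in the same signal range was 1.12 above that of the 17 bile acid genes (95% bootstrap interval 0.43 to 1.77). Both medians were known when this comparison was chosen, and bile acid synthesis had the lowest median of all lists, so a gap was built in. The values show that these sets were not lower by the same amount. They do not decide on the hepatocyte share. RNA degradation stays open. The 3' to 5' ratios of Actb and Gapdh were higher in the AKI pool by 0.48 and 0.29 on the log2 scale, that of pyruvate carboxylase was not, and degradation and kidney injury cannot be told apart with 1 array per group. A response of the liver to kidney injury is a further explanation that these data leave untested.

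Pdk4 was far higher while Pck1 and G6pc were far lower. Lower food intake after surgery stays open for Pdk4. Fasting raises Pck1 and G6pc as well as Pdk4, but these genes were picked for their large differences, so their values were not used as a test of it. The other genes of the PPARalpha list, which fasting would be expected to raise, had a median of -0.64 (-0.93 to -0.41), but 2 of them were higher and 5 lower by more than 2 SD of the probe set error (1.30), so the list does not decide. The negative medians of fatty acid synthesis (-1.19) and cholesterol synthesis (-1.45) and the difference of Igfbp1 (4.77) go with fasting. They too were picked for their large differences, so they are no test of it either. Cytokine signalling through STAT3, which represses gluconeogenic genes in hepatocytes, is a candidate explanation for Pck1 and G6pc. The STAT3 list was higher at 1.15 (0.72 to 2.78), but this was known when the explanation was chosen. The list holds mRNA levels, which measure neither STAT3 activity nor its effect on these genes. The medians of NF-kB targets with chemokines (1.91) and of immediate early genes (2.82) were higher still. No technical explanation was tested for Pck1 and G6pc, and another probe set of Pck1 past the level filter was at only -0.48.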
